A study of Homo sapiens with 3 samples.

How the data were processed

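The series measured which RNAs came down with TINCR, a long non-coding RNA induced during epidermal differentiation, in human keratinocytes at day 5 of differentiation. Cells were crosslinked with 1% glutaraldehyde for 10 min. TINCR was then captured with biotinylated oligonucleotides tiled along it, in 2 separate sets called the even and the odd pool, and the captured RNA was sequenced beside input RNA (RNA interactome analysis by sequencing, RIA-seq). Per the labels' protocols, cDNA was made with the Ovation-v2 kit, sheared to about 130 bp, amplified by 15 rounds of PCR and sequenced on a GAIIx. The labels put 1 library in each of the 3 groups, so no difference between pull-down and input has a replicate check, and no p-value is given.

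The data used were 1 deposited table of exon bins of 100 bp that were enriched in the pull-down. Per the submitters' processing notes, the reads were handled with TopHat and bedtools on hg18; versions, counting rules and strand settings are not given in the sources used here. The read counts per bin and library were used as the authors deposited them. The RPKM values in the deposited table are the count divided by the bin length and by a fixed total per library, which was checked by recomputing them. The ratio column of the deposited table, the authors' enrichment score, is the lower of the even over input and the odd over input RPKM ratios of a bin, and the deposited log2 column is its logarithm. Both were recomputed for each bin without a difference. The rule by which bins were kept is not given in the sources used here. The lowest score listed was 1.64, and no listed bin had 0 reads in a library. Only enriched bins are listed, so nothing can be said here about RNAs that were not enriched, and no enrichment of a gene group against the whole transcriptome was tested.

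Library totals were recovered from count and RPKM: 5957674 reads for the even pool, 14858502 for the odd pool and 17947128 for input. From these, the ratio of each pool to input was computed for each bin with an exact conditional interval at 95% confidence (Clopper-Pearson, for the share of a bin's reads that came from the pool). Reads passed through PCR without molecular identifiers, so these intervals cover counting error only. No pseudocount was added, since no count was 0. A gene was scored by its listed bin with the highest enrichment score. Bins that touched on 1 gene were joined into regions. Bins on chromosome Y and of XIST were left out throughout.

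Coordinates are those of the deposited table on hg18, written 1-based. Exons carry the table's own index, which counts from 0 at the lowest coordinate, so that index 0 is the last exon of a minus-strand transcript. No genome or annotation of that build was used, so coding and untranslated parts of exons are not told apart. Current symbols and gene types came from a RefSeq table of GRCh38.p14, used for names only. In it 1761 of the 1809 listed genes were matched by transcript accession, 31 by symbol and 7 by synonym, and 10 were unmatched. Listed bins overlapped another listed bin in 196 cases. In 16 bins the strand column differed from the strand in the exon's name; they were left out of the count of last exons.

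Before the data were examined, 15 gene lists were fixed: cornified envelope, suprabasal keratins and cell adhesion, barrier lipids, epidermal proteases and inhibitors, differentiation regulators, epidermal calcium binding, basal and progenitor genes, proliferation, ribosomal proteins, abundant housekeeping genes, long non-coding RNAs, Staufen and RNA decay, and markers of melanocytes, fibroblasts and immune or Langerhans cells. For the 10 lists with at least 5 listed members, the median gene score was placed among 10000 random lists of the same size. These were drawn from the listed genes and matched on the input RPKM of each gene's highest-scoring bin. That value is also the divisor of the score, so genes were not matched on their whole input level. Matching asked for 5 strata of it, and ties left 4. These percentiles describe these libraries and are not tests between conditions. The genes named were also fixed by rule: TINCR, the 15 genes with the highest score, the 5 with the most bins, up to 4 highest members of each list, and the 5 genes with the largest difference between the pools in each direction. Some genes that this rule takes are not reported here. Names outside that rule were chosen after their values were seen, and are marked so.

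The pools were compared by the Pearson correlation of log2 ratios across bins, with a bootstrap interval of 2000 draws. Since both pools are divided by the same input, 50 sets of unchanged pools were simulated from the input RPKM of the listed bins and put through the same score minimum. Alternatives fixed beforehand were a stricter score minimum, filters on low pool or input values, more bins per gene, gaps between joined bins, rank correlation, other scalings, each pool alone and other measures or matchings for the lists. Others, chosen after the data were seen, were added pseudocounts, totals without mitochondrial-like reads, intervals above 1 in both pools, a minimum of 10 input reads, and leaving out KRT14, overlapping bins or bins with repeated counts.

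The computations were tested on simulated data. No score minimum was applied to the simulated bins. The shares of bins below therefore do not give the error among the listed bins, which were selected as enriched. Intervals held the simulated ratio in 98.4% of 3325 even-pool bins and 98.1% of 3451 odd-pool bins. Of bins raised 4-fold in both pools, 100% of 36 with at least 20 input reads and 32.3% of 164 with fewer had both lower bounds above 1, against 0.0885% of 3391 unchanged bins. Lists of 10 random genes fell outside the 2.5th to 97.5th percentiles in 5% of 200 draws, and lists of 10 genes raised 2-fold lay above the 97.5th percentile in 57% of 100 draws. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.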

Results

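RNA captured with 2 oligonucleotide pools against TINCR was compared with input RNA from differentiated human keratinocytes, the main cell type of the epidermis, in 1 library each. The listed bins held counts worth 32.3% of the even-pool library, 20.1% of the odd-pool library and 2.69% of the input library. Bins of the mitochondrial-like genes MTRNR2L and MIR4485 alone held 27.5%, 9.24% and 2.41% of these libraries, in the same order. These shares and those below are summed bin counts over the library total, so a read counted in more than 1 bin would enter each time. A median bin had 9 reads in the even pool, 16 in the odd pool and 4 in input. In 979 of 3591 bins (27.3%) the input count was a single read, and against 1 input read each read of the even pool added 3.01 and each read of the odd pool 1.21 to the ratio.

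The captured RNA itself was the first comparison, since it shows whether the oligonucleotides retrieved their target. TINCR, listed under its older symbol PLAC2 with transcript NR_027064, lies on the minus strand of chromosome 19 between 5509178 and 5518975 on hg18. Its 34 listed bins were 29 of the 33 bin positions up to the last one listed in the last exon (index 0), 2 in the middle exon and 3 in the first exon. Summed over these bins, TINCR was 271-fold higher in the even pool than in input (95% interval 257 to 286) and 607-fold higher in the odd pool (575 to 640). It took 2.09% of the even-pool library and 4.68% of the odd-pool library, against 0.00771% of input. All 34 bins had lower bounds above 1 in both pools, and they made up 28 of the 30 highest scores in the table.

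Enrichment ran along all 3 exons of TINCR and differed in shape between the pools. The odd ratio was above the even ratio in 32 of 34 bins. The exceptions were the 2 bins nearest the 3' end: at 5509178 to 5509277 the ratio was 275 in the even pool and 65.2 in the odd pool, and at 5509278 to 5509377 it was 293 and 119. Bin ratios ranged from 18.1 to 467 in the even pool and from 65.2 to 9778 in the odd pool. The highest odd ratio, at 5510878 to 5510977, rested on 2 input reads.

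**Figure D1:**
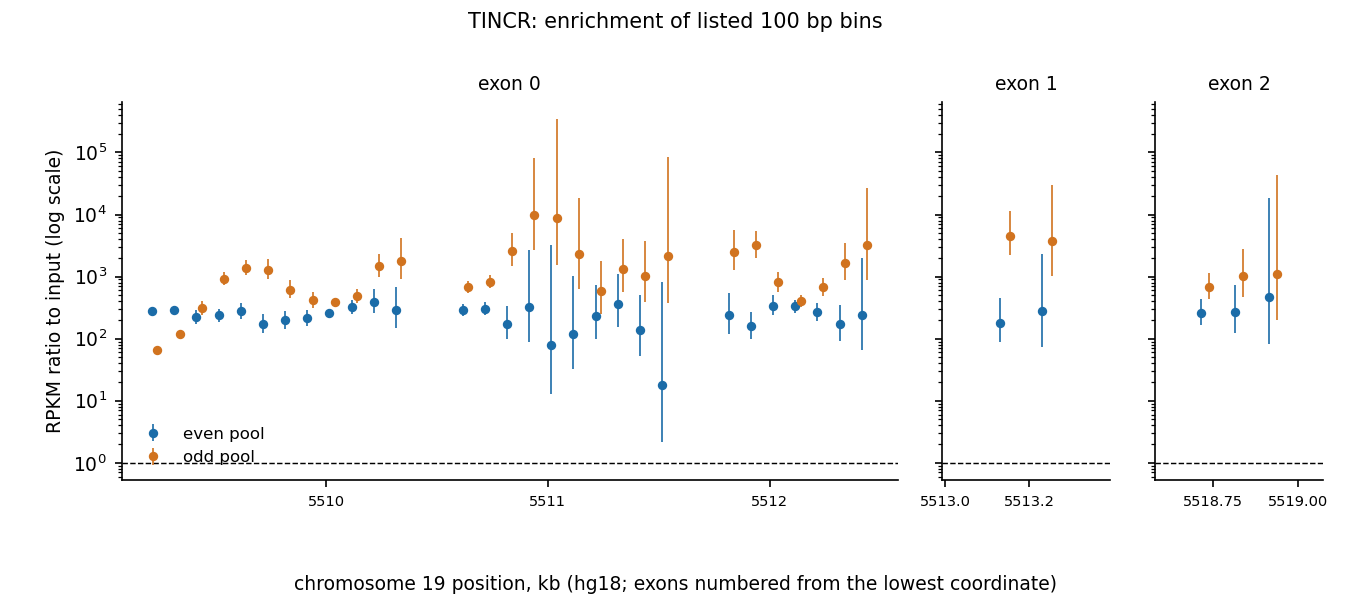
RPKM ratio to input (log scale) of each listed 100 bp bin of TINCR against its position on chromosome 19 of hg18, in 3 panels for the 3 exons, for the even pool (blue) and the odd pool (orange). Bars are 95% exact counting intervals from 1 library per group, and the dashed line marks a ratio of 1; all 34 bins lie above it, and the odd ratio is the higher one in 32.

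The second comparison asked which other RNAs were enriched over input in both pools. No pull-down without TINCR was analysed here, so RNA captured by the oligonucleotides themselves cannot be told apart from RNA bound to TINCR. Exon bins of 1809 genes were listed, TINCR included, and 1695 of them (93.7%) are typed as protein-coding in current RefSeq, where TINCR itself is so typed. There were 42 long non-coding RNA genes, 45 transcribed pseudogenes and 4 microRNA genes. Most genes had few bins: 1025 genes had 1 bin, 784 had at least 2 and 135 at least 5. The bins formed 2594 regions, of which 1893 were a single bin and 178 held at least 3. Outside TINCR the longest regions of touching bins were in LOC100505815 (900 bp), ARHGEF5 (800 bp) and GNAL (700 bp), named after their values were seen.

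The median ratio to input was 6.02 in the even pool (quartiles 3.01 and 14.6) and 4.23 in the odd pool (2.42 and 9.33), and the median score was 3.01. Summed over all genes but TINCR and the mitochondrial-like ones the order was the other way, with 9.52 in the even pool (9.42 to 9.62) and 22.5 in the odd pool (22.3 to 22.7). Most of that gap came from KRT14, whose counts are uncertain: without it, a setting chosen after the data were seen, the values were 9.99 (9.89 to 10.1) and 13.5 (13.3 to 13.6). In pools simulated without any change, bins that passed the same score minimum had median ratios of 3.01 (even pool) and 2.42 (odd pool). Their median score was 2.42 with a 95th percentile of 4.83, and 195 of the 3591 bins passed per draw. The draws came from the listed bins only and not from all exon bins. So 195 is not the number of listed bins that unchanged RNA would give. Both lower bounds were above 1 in 1473 bins (41.0%), which lay in 764 genes. This share followed the input depth. It was 15.9% of 979 bins with 1 input read and 27.2% of 1022 bins with 2 to 4. It was 52.8% of 1070 bins with 5 to 19 and 91.2% of 520 bins with 20 or more. All listed bins scored at least 1.64, and intervals narrow with more reads. The rise is therefore partly built in and does not measure how often enrichment is real.

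Outside TINCR, the highest score belonged to XRCC1. This gene, which encodes a scaffold protein of DNA single-strand break repair, had a score of 171.7 at chromosome 19, 48742876 to 48742975, with a ratio of 171.7 in the even pool (46.5 to 1435) and 876 in the odd pool (242 to 7243). The transcriptional repressor CIC scored 135.6 at chromosome 19, 47490027 to 47490126. RAB1B, a small GTPase of transport from the endoplasmic reticulum to the Golgi, scored 129.5 at chromosome 11, 65800691 to 65800790. SAP130, a subunit of the SIN3 corepressor complex, scored 108.4 at chromosome 2, 128470394 to 128470493. PTMS scored 99.4 at chromosome 12, 6749919 to 6750018, with 1300 in the odd pool.

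The others among the 15 highest genes were the endosomal GTPase RAB5B (66.3), the Wnt receptor FZD1 (60.2), the cornified-layer protein KPRP (59.2), the death receptor FAS (57.2), TNKS1BP1 (56.8), CHPF (54.2), SSR1 (51.2), TTYH3 (51.2) and the calcium sensor STIM2 (46.7). For each of these genes both lower bounds at its highest bin were above 1. Each score is the gene's single highest bin, and the planned median over the gene's bins was far lower for several. The median was 12.4 for CIC, 2.85 for RAB5B, 3.01 for KPRP, 4.38 for FAS, 5.02 for TNKS1BP1, 6.03 for SSR1 and 7.14 for STIM2. XRCC1, RAB1B and FZD1 had only 1 listed bin each, so for them the median is the score itself and checks nothing. With 1 read added to every count, a setting chosen after the data were seen, CIC fell to 69.3, RAB1B to 66.3, FZD1 to 30.8 and KPRP to 30.2. The sizes are poorly fixed, since the highest bins had 1 to 3 input reads: for CIC the even-pool interval ran from 23.1 to 5472. Of the 67 bins outside TINCR among the 100 highest scores, 39 had 1 input read and 55 had 1 to 3.

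**Figure D2:**
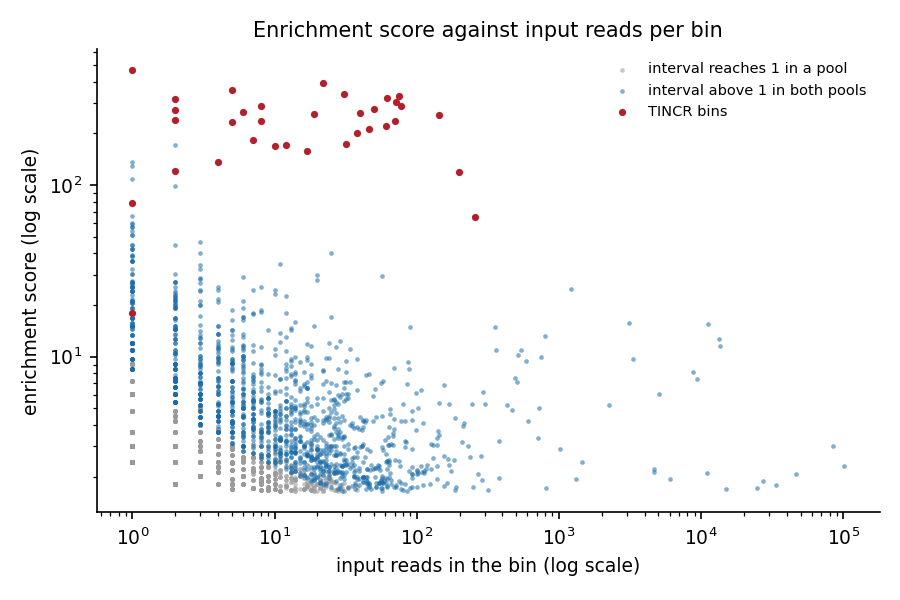
Enrichment score of each listed bin (log scale) against its input reads (log scale), for bins whose 95% exact counting intervals lie above 1 in both pools (blue), other bins (grey) and TINCR bins (red). Of the 67 bins outside TINCR among the 100 highest scores, 55 lie at 1 to 3 input reads; 91.2% of the 520 bins with 20 or more input reads have both intervals above 1.

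After TINCR, the genes with the most bins were RAB11FIP1 (19), an effector of recycling endosomes, the hemidesmosome integrin ITGB4 (16), the transcription factor ELF4 (15) and TP63 (13), the master regulator of stratified epithelia. Both lower bounds were above 1 in 12 of the TP63 bins, 5 of ITGB4, 4 of ELF4 and 4 of RAB11FIP1. Pool counts repeated between bins of TP63, ELF4 and RAB11FIP1. In 8 TP63 bins over 1100 bp on chromosome 3, between 191080947 and 191082046, the even count was 26 and the odd count 32 each time, while input varied from 1 to 21 reads. The TP63 score of 38.7 came from such a bin with 1 input read, and 8 ELF4 and 4 RAB11FIP1 bins also shared both pool counts with a distant bin. The even count alone recurred more widely: it was 6 in most ELF4 bins and 4 in most RAB11FIP1 bins. Further TP63 bins in that stretch or next to it had 27 even reads and 32 or 34 odd reads. Whether the same reads were counted in each of these bins is not given in the sources used here, so these bins cannot be counted as separate support.

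The lists fixed beforehand asked whether epidermal differentiation genes stood out among the RNAs that came down. Cornified envelope genes, which build the tough shell of the outermost cells, had 17 of 49 members listed, 15 of them with both lower bounds above 1 at some bin. Over all 1809 listed genes, 764 had such a bin. The counts per list, here and below, were not matched on number of bins or input depth. KPRP scored 59.2 at 1 input read. SPRR1B, a crosslinked envelope precursor, scored 14.8 at chromosome 1, 151271527 to 151271626, with 14.8 in the even pool (13.2 to 16.6) and 55.2 in the odd pool (49.7 to 61.5). Corneodesmosin CDSN scored 13.6 and envoplakin EVPL 8.499 (even pool 5.46 to 13.6). SPRR1A and SPRR1B, and likewise the 5 listed SPRR2 genes, are near-identical copies, and their split of reads is uncertain. All of these copies are among the 15, so the 15 are not separate support. The list's median score of 3.89 lay at the 86.0th percentile of random lists.

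Suprabasal keratin and cell adhesion genes had 13 of 27 members listed, 8 with both lower bounds above 1. Among the highest were KRT80 (7.39), the tight junction protein OCLN (6.02) and the desmosomal plakophilin PKP1 (5.56). The OCLN value rested on 1 input read, and its interval reached below 1 in both pools. PKP1 was 5.56-fold higher in the even pool (3.38 to 9.34) and 8.87-fold higher in the odd pool (5.87 to 13.9). The list lay at the 81.9th percentile.

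Epidermal proteases and their inhibitors had 6 of 29 members listed, all 6 with both lower bounds above 1. The kallikrein KLK10 scored 5.28 (4.66 to 6.0 in the odd pool) on 304 input reads. CST6 scored 4.83, the cornification caspase CASP14 4.29 and the elastase inhibitor PI3 4.23. The list lay at the 85.7th percentile. Barrier lipid genes had 9 of 39 members listed, 3 with both lower bounds above 1, and lay at the 27.4th percentile. Among them were the lipoxygenases ALOXE3 (9.04) and ALOX12B (5.75), the ceramide desaturase DEGS1 (6.34) and the fatty acid elongase ELOVL1 (3.22). The ALOXE3 bin had 3 even-pool reads and 1 input read, and its even interval reached below 1.

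Differentiation regulators had 8 of 28 members listed, 3 with both lower bounds above 1, and lay at the 12.8th percentile. NOTCH3, a receptor of the Notch pathway, scored 25.4 with 25.6 in the even pool (9.13 to 99.3) and 25.4 in the odd pool (9.55 to 95.3). TFAP2A scored 4.83 at a bin whose intervals reached below 1 in both pools, but 1 of its 3 bins had both lower bounds above 1. RORA scored 2.78. Epidermal calcium-binding genes had 4 of 16 members listed, too few for a percentile. They were the calcium pump ATP2A2 (5.80), S100A11 (4.91), S100A7 (3.62, on 1 input read and with intervals that reached below 1) and S100A16 (2.56).

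Genes of other states and cell types were listed too. Basal and progenitor genes had 10 of 20 members listed, 7 with both lower bounds above 1, at the 73.7th percentile: TP63 (38.7), ITGB4 (15.1), the basal keratin KRT14 (6.22) and ITGA3 (6.02) were the highest. All but KRT14 had 1 input read at that bin, the even interval of ITGA3 reached below 1, and KRT14 has near-identical copies in the genome, so its counts are uncertain. None of 24 proliferation genes, 8 melanocyte markers and 8 immune or Langerhans markers was listed, which says only that they did not pass the table's own rule. Of 13 fibroblast markers, FN1 (6.64) and COL1A1 (1.81) were listed; keratinocytes also make FN1, and the COL1A1 intervals reached below 1.

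Among general lists, Staufen and RNA decay genes had 10 of 19 members listed, 4 with both lower bounds above 1, at the 47.4th percentile. The RNA-editing enzyme ADAR scored 24.4 (13.0 to 51.7 in the odd pool), and the nonsense-mediated decay factors SMG6 and SMG5 scored 16.9 and 4.83. The SMG5 intervals at that bin reached below 1, while 2 of its 5 bins had both lower bounds above 1. STAU1, which encodes the double-stranded RNA-binding protein Staufen1 and was named after its value was seen, scored 2.41, and its even interval reached below 1. Ribosomal protein genes had 7 of 76 members listed, 4 with both lower bounds above 1, at the 73.6th percentile, led by RPS3 (5.03), RPL28 (4.22) and RPL10A (4.03). Housekeeping genes had 7 of 25, 4 with both lower bounds above 1, at the 4.72nd percentile. They were led by PKM2 (9.04, on 1 input read), ACTB (5.33), PFN1 (2.34) and LDHA (2.26). The even intervals of PKM2 and LDHA reached below 1 at these bins, while 4 of the 8 PKM2 bins had both lower bounds above 1. Long non-coding RNAs had 5 of 17, 2 with both lower bounds above 1, at the 29.6th percentile, led by H19 (6.02), HOTAIR (6.02), KCNQ1OT1 (3.01) and SNHG1 (2.54); at these bins the even intervals of H19, HOTAIR and KCNQ1OT1 reached below 1. Ribosomal protein and housekeeping genes have many processed copies, so their counts are uncertain.

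None of the 10 tested lists lay outside the 2.5th to 97.5th percentiles of random lists. With random lists matched on the number of bins, which was planned, the cornified envelope list moved to the 41.9th percentile, the basal list to the 40.4th, the protease list to the 46.6th and the housekeeping list to the 1.14th. The Staufen and RNA decay list moved to the 5.01st percentile under that matching, to the 99.96th when genes were ranked by number of bins and to the 98.06th at the stricter score minimum. The suprabasal list moved to 29.22 when genes were ranked by number of bins and to 9.96 at the stricter score minimum.

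**Figure D3:**
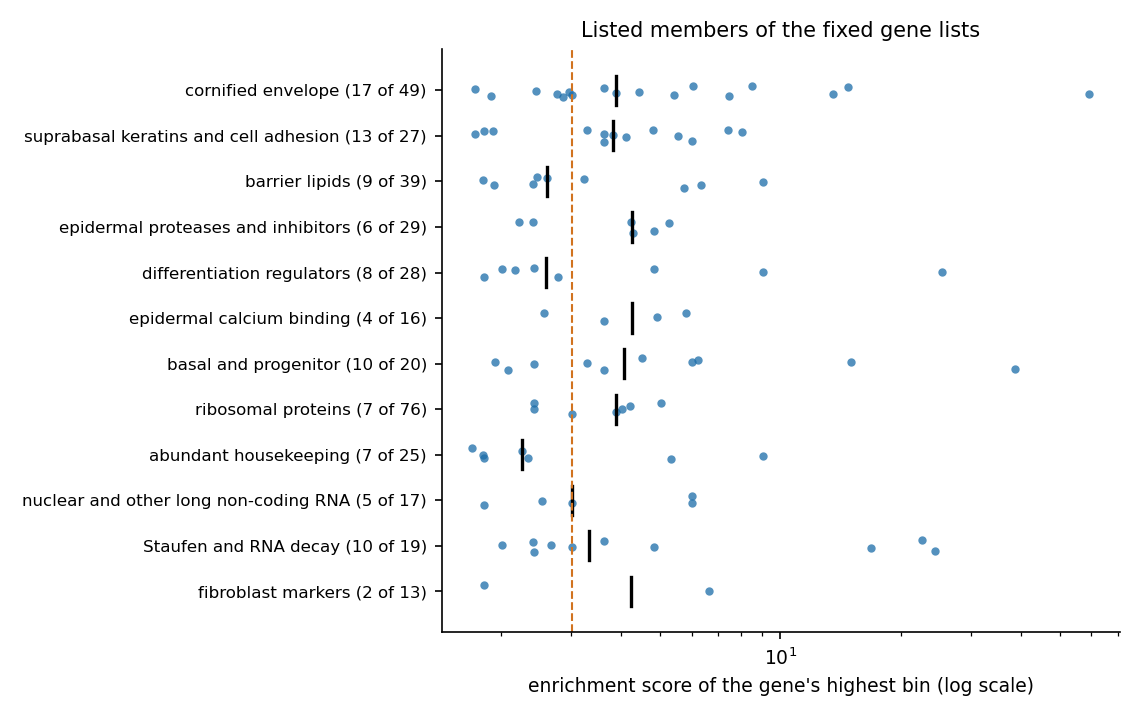
Enrichment score of the highest bin (log scale) of each listed member of the gene lists with at least 1 listed gene; points are genes, black bars list medians and the dashed line the median of all 1809 listed genes. Counts in brackets give listed members out of list size; medians of the 10 tested lists run from 2.26 to 4.26, against 3.02 for all listed genes.

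The third comparison set the even against the odd pool, since the pools are separate sets of oligonucleotides and each serves as a check on the other. Outside TINCR, single genes stood out in 1 pool. KRT14 was 115-fold higher than input in the odd pool over its 5 bins (112 to 119) and took 2.83% of that library, against 4.67-fold in the even pool (4.49 to 4.85). The lipoxygenase gene ALOXE3, at chromosome 17, 7940343 to 7940442, had 5607 odd-pool reads, 3 even-pool reads and 1 input read. The desmosomal plakoglobin gene JUP, named after its values were seen, reached 131-fold in the odd pool at a bin with 4.79-fold in the even pool.

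APCDD1 was 519-fold higher in the odd pool and 7.23-fold in the even pool. POLR2J2 and UPK3BL were 629-fold and 234-fold higher in the odd pool, and their even intervals reached below 1. Their bins on chromosome 7 overlap between 102065010 and 102065032, so their counts are uncertain. The POLR2J2 value rested on 1 input read (odd interval 112 to 24903). In the other direction, the even ratio was 277 for AMOTL2, 221 for TRIM41, 187 for FAM83A, 184 for CENPO and 182 for DDX39B. Their odd ratios were 2.42 to 3.62, with intervals that reached below 1. These bins had 1 to 3 input reads, so the sizes are poorly fixed: the even interval of AMOTL2 ran from 48.5 to 11064.

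Across bins the log2 ratios of the pools were weakly correlated, with a Pearson r of 0.216 (bootstrap interval 0.168 to 0.261) and a Spearman rho of 0.127. Bins are not independent replicates, and the listed bins were selected for both pools. Without the TINCR bins r was 0.0980, and without TINCR among bins with at least 10 input reads it was 0.00271. Unchanged pools that share the input gave r = 0.392 in the simulation. That value rests on the about 195 bins that passed per draw, so it cannot be set directly against the observed r. The covariance was 0.573 against 0.134 simulated, a difference of 0.439, which fell to 0.0885 without TINCR; the selection of bins keeps this difference from being a clean measure of shared enrichment. Ratios lay within 2-fold of each other in 43.6% of bins and within 8-fold in 85.8%. The even ratio was more than 8-fold higher in 334 bins and the odd ratio in 175.

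**Figure D4:**
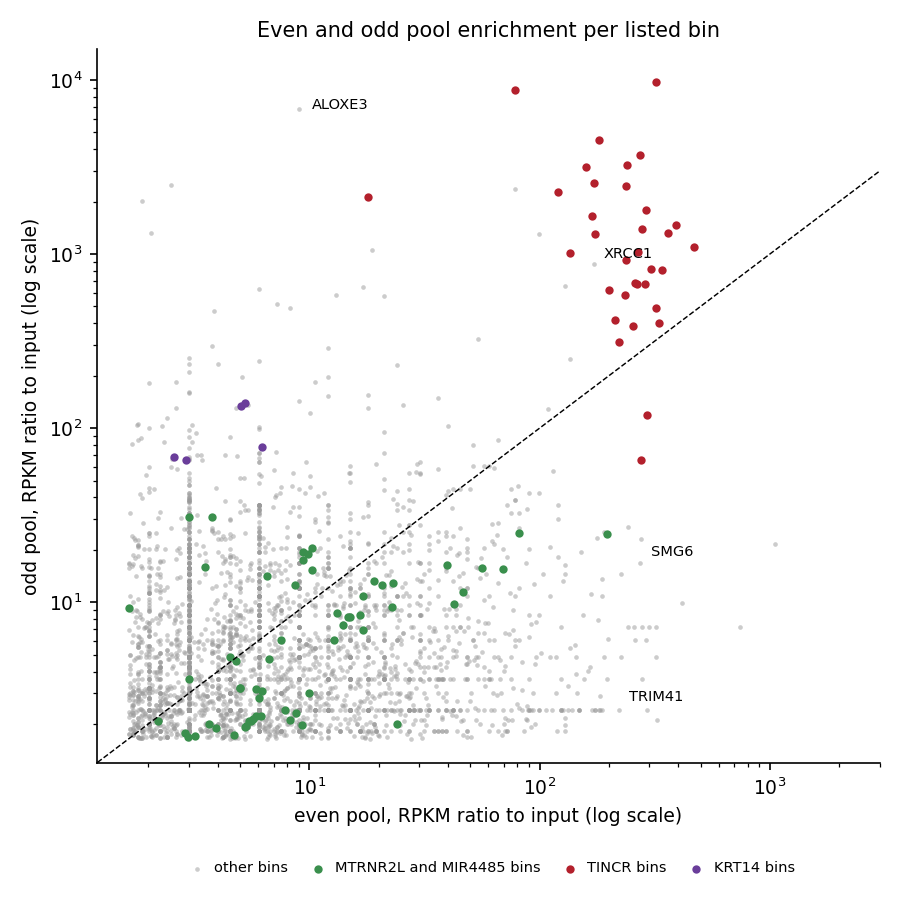
Ratio to input in the odd pool against that in the even pool for each listed bin, both on log scales, with the dashed line at equal ratios; bins of TINCR (red), KRT14 (purple) and MTRNR2L or MIR4485 (green) are marked. TINCR bins lie high in both pools, while the 5 KRT14 bins lie at 65.5 to 139 in the odd pool and 2.58 to 6.22 in the even pool.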

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

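Alternatives with both lower bounds above 1, at least 10 input reads, added reads, changed totals, KRT14 left out, overlapping bins or repeated counts were chosen after the data were seen; the others were planned. No paired analysis was possible because each group has 1 library. Multiples of 0.5 and 5 of the pseudocount were not run, since none was used; scaling both pools to the same median cannot change r. The cause of each change was not tested, except where fewer bins or genes enter by construction.

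The 3591 bins became 1518 at a score of at least 2 times the lowest and 1473 with both lower bounds above 1. The 1809 genes became 882 and 764 under these settings, 784 with at least 2 bins and 368 with at least 3. Other settings for bins, genes and regions stayed within 1.5-fold. The pools' r of 0.216 became 0.127 by ranks, 0.0980 without TINCR, 0.675 for RPKM not divided by input, 0.283 for bins with at least 10 input reads and 0.00271 for those without TINCR. With MTRNR2L and MIR4485 reads out of the totals the median even ratio of 6.02 became 8.12 and the median odd ratio of 4.23 became 4.55; at 10 input reads or more they were 4.54 and 3.61.

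From 0 lists outside the 2.5th to 97.5th percentiles, 1 of 10 lay outside when ranking genes by number of bins, matching on number of bins or not matching, and 1 of 4 at the stricter score. Matching on number of bins moved cornified envelope to 41.86, proteases to 46.59, basal genes to 40.42, Staufen and RNA decay to 5.01 and housekeeping to 1.14 (2.06 unmatched). Number of bins put suprabasal genes at 29.22 and Staufen and RNA decay at 99.96. The stricter score put suprabasal genes at 9.96, basal genes at 41.21 and Staufen and RNA decay at 98.06. With both lower bounds above 1, cornified envelope was at 47.22 and basal genes at 23.64. Of 70 named genes, 19 moved beyond their counting interval with the median over bins, 12 with the even pool alone and 15 with the odd pool alone. With 1 read added CIC went from 135.6 to 69.3, RAB1B from 129.5 to 66.3, FZD1 from 60.2 to 30.8 and KPRP from 59.2 to 30.2. Bins with 1 input read had intervals above 1 in both pools in 15.9% of cases, against 91.2% of bins with 20 or more. This contrast is partly built in, since only bins listed as enriched enter it.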

Other observations

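Tests of MTRNR2L read placement and of library totals, the list of well-covered genes, the last-exon counts and the repeated counts were chosen after the results were seen.

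Among the 294 genes with a listed bin of at least 20 input reads, leaving out TINCR and the mitochondrial-like genes, 49 had a score of at least 5 there and 7 of at least 10. The highest was TNS4, a focal adhesion protein of epithelia, at 40.0-fold in the even pool (26.6 to 62.7) and 43.5-fold in the odd pool (29.3 to 67.6) at chromosome 17, 35897214 to 35897313. The nuclear import receptor TNPO2 followed with a score of 30.02, the amino acid transporter SLC7A8 with 28.2, the stress-induced keratin KRT6A with 17.0, the protocadherin FAT1 with 14.9, SPRR1B with 14.8 and the serine protease PRSS27 with 11.4. FAT1 had close values in the pools, 14.9 (11.8 to 18.9) and 15.4 (12.4 to 19.3), on 90 input reads. KRT6A and KRT6C (8.48) are near-identical, so their reads are uncertain. These genes have narrower intervals than the 15 highest scores.

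On minus-strand transcripts most listed bins lay in the last exon. On minus-strand transcripts, leaving out TINCR and mitochondrial-like genes, 933 of 1705 bins (54.7%, Clopper-Pearson 52.3 to 57.1) were in the exon of lowest coordinate, which is the last exon. On plus-strand transcripts 153 of 1776 (8.61%, 7.35 to 10.0) were in the exon of lowest coordinate, which is the first. In the minus-strand last exons, the median bin started 1000 bp from the 3' end and 32.6% of bins within 500 bp. How exon length is spread over these transcripts was not used here, so no excess over length was computed.

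The pools differed at many listed bins. Counting error alone was tested by the share of bins whose interval of even over odd left out the median: it was 46.6%, above the 20% named beforehand as the bound against it. Whole RNAs captured by 1 pool may account for part: between 2 exons of 1 gene the even over odd difference correlated at 0.361 across 170 genes (0.194 to 0.513), neither clearly above 0.3 nor below 0.1. Different exon indexes do not assure separate reads: TP63 bins of index 8 and 10 in 1 stretch had equal counts, 26 even and 32 odd. Local products of 1 library, such as PCR duplicates, are also open, since touching bins correlated at 0.783 across 312 genes (0.718 to 0.829), but touching bins can share reads; off-target binding by the oligonucleotides of 1 pool was not tested.

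MTRNR2L genes, nuclear copies of the mitochondrial 16S ribosomal RNA, and MIR4485 held 60 listed bins. Their summed counts were 27.5% of the even-pool library, 9.24% of the odd-pool library and 2.41% of input, 11.4-fold and 3.84-fold above input. Reads counted in more than 1 of these bins would raise these shares. A candidate explanation is that mitochondrial reads were placed on the copies wherever the sequence is near-identical. In 6 of 6 copies with at least 5 listed bins, the highest input count was over 100 times the lowest (median range 10458, against 7.5 in 44 other exons), as that would give. The median listed bin had only 4 input reads, which limits the range other exons can show. The contrast with them therefore cannot decide the question. Taking these summed counts out of the totals raises even ratios by a factor of 1.35 and odd ratios by 1.08, if each read was counted in 1 bin only. The ratio of the even to the odd median then goes from 1.43 to 1.79. On these counts, their share of the totals cannot be what puts the even median above the odd one. Whether mitochondrial RNA came down with TINCR or with the oligonucleotides stays open, as no pull-down without TINCR was analysed here, and no biological explanation was tested for either pattern.

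Equal pool counts recurred in distant bins. Among 2703 bins with at least 3 reads in both pools, 91 of 3691 pairs 300 bp to 100 kb apart had the same even and the same odd count (2.47%). This compares with 189 of 209691 pairs over 1 Mb apart (0.0901%), a ratio of 27.4. Near pairs are more often of 1 gene, and pairs were not matched on count, so the ratio does not measure repeated counting alone. The near pairs with equal counts took in 68 bins in 18 genes, with 8 bins each in ELF4, ERAP1 and TP63 and 6 in BMPR2.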
